A study of Homo sapiens with 20 samples.

How the data were processed

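RNA was measured in A549 cells, an established human line derived from a lung carcinoma and used as a model of alveolar type II epithelium. Per the labels, the cells were grown on flexible collagen-coated plates and were left static, stretched to 20% elongation, treated with 20 ng/ml tumour necrosis factor (TNF), treated with 1 µg/ml bacterial lipopolysaccharide (LPS), or given TNF and stretch together. Each condition was sampled at 1 h and at 4 h, which gives 10 groups of 2 arrays and 20 arrays in all. One Affymetrix Human Genome Focus array was hybridised per sample.

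The deposited values are signal intensity per probe set on a linear scale, with 8793 probe sets per array. Neither the labels nor the file headers state the summary algorithm or the scaling target. In the deposited intensity values the mean after removing 2% of the probe sets from each end lay between 150.165 and 150.199 on every array, a spread of 0.0224%, as it does for arrays scaled to a common level. The median intensity per array was between 39.7 and 48.5. The deposited table holds no detection calls. The other deposited files are text records of each array's hybridisation, which hold no measurement and were read only for the scan day and the chip lot. The record of static replicate 1 at 4 h, a control of every comparison with static at 4 h, was blank, and that array was placed in its block by its label alone. For arrays there is no depth in counts, and the number of arrays limits the precision.

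Probe sets were paired with genes through the probe table provided, which gave 1 gene symbol for 7846 probe sets and several for 388. It did not name 559, of which 41 were Affymetrix controls. Probe sets whose identifier ends in _x_at or _s_at can match several transcripts. All 47 control probe sets were left out. A probe set was tested if at least 2 of the 20 arrays exceeded the median of all values, 43.8, which left 5357 probe sets, 4824 of them with 1 symbol, for 4751 genes. The values tested were log2(signal + 8.7), the added value being the 20th percentile of all signals. It pulls the log2 differences of dim probe sets towards 0, so they are smaller than the ratio of the signals.

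Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with 10 group means was fitted to all 20 arrays (10 residual degrees of freedom), followed by eBayes with a trend in the variance. Every test was two-sided, and p was adjusted by the Benjamini-Hochberg method over the 5357 probe sets within each of 17 comparisons, with a threshold of 0.05. If nothing changed, a share of 0.05 of the 5357 probe sets would be expected to have an unadjusted p under 0.05. A count below that share is no sign of change, and one above it is no test, since probe sets are not independent. There were 8 comparisons of a stimulus with the static control of its time, and 9 direct tests between stimuli, of combinations or of times. Unless stated otherwise, differences are on the log2 scale with the standard error (SE) from limma, and signals are given with the SD over the 2 arrays of a group.

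The replicate block has 3 levels, replicate 1 at 1 h, replicate 1 at 4 h and replicate 2 of all groups, set by replicate number and time. Per the labels all replicate 2 arrays share 1 experiment day, as do the 4 replicate 1 arrays at 4 h with a date. The replicate 1 arrays at 1 h do not: the 3 with a date fall on 2 days, LPS apart from stretch and TNF. The other 3 replicate 1 arrays, static at both times and TNF+stretch at 1 h, have no date. The scan records parted the 19 arrays with a record into the same 3 levels, and the chip lot parted replicate 1 from replicate 2. To check the pairing, the difference between replicate 1 and replicate 2 was correlated across probe sets between groups. Probe sets are not independent replicates. Within a time the correlation was between 0.433 and 0.825 over 20 pairs of groups, with a median of 0.722, and across times its median was 0.648. The fit with this replicate block (8 residual degrees of freedom) is given beside each result whose call it changed or whose count it moved by more than 1.5 times. It gave a median SE of 0.238, compared with 0.387 without the block. Without the block the p-values measure the spread between replicate 1 and replicate 2, which differ in scan day and chip lot on the arrays with a record. With the block they measure the spread left after it. All arrays are of 1 cell line, and the labels do not say if the replicates were independent cultures.

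Both fits were tested on simulated data for the comparison of TNF with static at 4 h, with 200 of 5357 probe sets changed in each of 10 simulations. The fit without the block recovered 6.70% of 2-fold and 61.44% of 4-fold changes, with a mean of 0.1 false calls. The fit with the block recovered 62.52% and 95.05%, with a mean of 8.4 false calls, 5.09% of its calls. The simulated values were drawn from the fit with the block, with its block effects, its spread and independent normal errors. Its model therefore holds in them by design, and they cannot show which fit suits the real arrays.

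A set of 23 gene lists was tested with camera from limma, with a preset correlation of 0.01 between genes and, beside it, with an estimated correlation. The p was adjusted over the lists within a comparison. A gene with several probe sets was counted by the one with the highest mean. Lists with fewer than 5 tested genes were counted and not tested. Members past the threshold are given after adjustment over all probe sets and also adjusted over the list alone. The lists, the 17 comparisons, the tests, the filter, the rule for named genes and the alternatives with quantile normalization of the gene values, a floor in place of the added value, no filter, the replicate block, the arrays of 1 time only and leaving out 1 array were all fixed before the data were examined. Leaving out 3 arrays with a GAPDH 3' to 5' ratio above 3, taking that ratio as a covariate, quantile normalization for the lists and applying the naming rule to the fit with the block were chosen after seeing the data.

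The rule for named genes took, for each stimulus against static, the 15 largest rises and the 10 largest falls past the threshold that had the same sign in both replicate pairs. For the other comparisons it took the 5 largest on each side. Where fewer than 5 passed, the 5 with the smallest p were also named as values that did not pass. Members of the lists could be named too, and TNF, TNFRSF1A, TLR4, CXCL8 and ICAM1 were named in every comparison with static if measured. With 2 arrays per group, no other splits of the samples were run for these comparisons. Intervals of medians over genes came from 2000 bootstrap resamples of the genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.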

Results

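The series measured gene expression in A549 alveolar epithelial cells after 3 kinds of stimulus that injured lung meets: the inflammatory cytokine TNF, the bacterial product LPS and cyclic mechanical stretch, with TNF and stretch also given together. Each of the 10 groups had 2 arrays (n = 2 throughout), and 5357 probe sets were bright enough to test. The 2 arrays of a group correlated at 0.836 to 0.924 across probe sets (median 0.896), while replicate 2 arrays of different groups correlated at a median of 0.964. Replicate 1 and replicate 2 differ in day, in chip lot and in the RNA ratios given next. The control probe sets for GAPDH and beta-actin give the ratio of signal at the 3' end to that at the 5' end of a transcript, which rises when RNA is degraded or incompletely copied. The median GAPDH ratio was 1.07 in replicate 1 and 1.84 in replicate 2, and the median actin ratio was 1.56 and 6.77. In the static and TNF groups at 1 h, however, both ratios were higher in replicate 1.

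**Figure D1:**
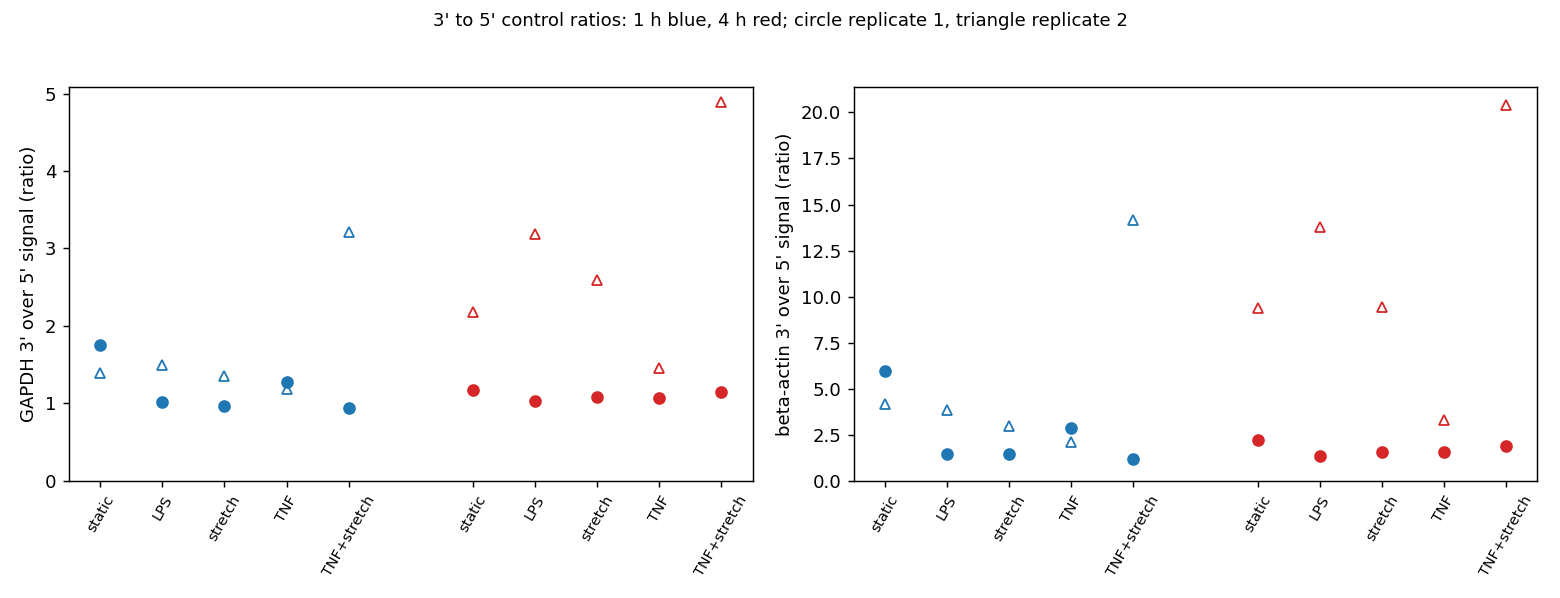
Ratio of 3' to 5' signal (y axis, linear) of the GAPDH (left) and beta-actin (right) control probe sets on each of the 20 arrays, by stimulus at 1 h (blue) and 4 h (red), with circles for replicate 1 and open triangles for replicate 2. The highest GAPDH ratio, 4.89, and the highest actin ratio, 20.4, both belong to replicate 2 of TNF+stretch at 4 h.

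TNF for 1 h raised a small set of inflammatory genes, which addresses what the cytokine does early. CCL20, a chemokine that attracts dendritic cells and lymphocytes, rose by 4.68 (SE 0.40, adjusted p = 0.000140), from a signal of 4.65 ± 0.778 to 339 ± 84.1 (SD, n = 2). Its static signal lies under the added value of 8.7, so the size of its difference from static, and from LPS or stretch where it is as dim, depends on that value. The added value pulls that difference towards 0. TNFAIP3, which encodes the NF-kB inhibitor A20, rose by 3.44 (SE 0.39, adjusted p = 0.00179). The cytokine IL6 rose by 2.85, and the neutrophil chemokines CXCL8, CXCL3 and CXCL2 rose by 2.80, 2.60 and 2.28. NFKBIA, which encodes the inhibitor IkB-alpha, rose by 2.19 from a signal of 1102 ± 185 to 5054 ± 752. ZFP36, whose product destabilises cytokine mRNA, rose by 1.90, and the transcription factor IRF1 rose by 1.53. These were all 9 probe sets past the threshold, all higher, and each was higher in both replicate pairs. The replicate block gave 14, 13 higher and 1 lower, and added EFNA1 at 2.91, CCL2 at 2.66 and ZNF443 at 2.23, with MYC at −0.82 (adjusted p = 0.0452 with the block). TNFRSF1A, the receptor for TNF, differed by 0.05 (SE 0.57), TLR4 by −0.21 (SE 0.49) and the adhesion molecule ICAM1 by 1.48 (SE 0.75), and none of them passed in either fit. The TNF gene itself was too dim to test, with a median signal of 16.25 over the 20 arrays.

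By list, the cytokines and chemokines rose as a group at 1 h of TNF: 5 of 20 tested members passed, 6 adjusted over the list alone (camera adjusted p = 1.77e-24, and 2.27e-05 with an estimated correlation). NF-kB target genes rose too, with 3 of 21 past the threshold and 6 adjusted over the list alone (adjusted p = 4.06e-21, and 0.000661 with an estimated correlation). In this list PTX3 had a difference of 2.19 and IER3 of 1.07, neither of which passed over all probe sets. Immediate early genes, the first genes transcribed after a stimulus, rose as a list (adjusted p = 1.08e-07, and 0.00736 with an estimated correlation), with ZFP36 the 1 of 31 that passed and 2 adjusted over the list alone. The last of these had an adjusted p of 0.105 with the block and an estimated correlation. Leaving out 1 array gave 5 probe sets without static replicate 2, 3 without static replicate 1, 2 without TNF replicate 2 and 3 without TNF replicate 1.

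**Figure D2:**
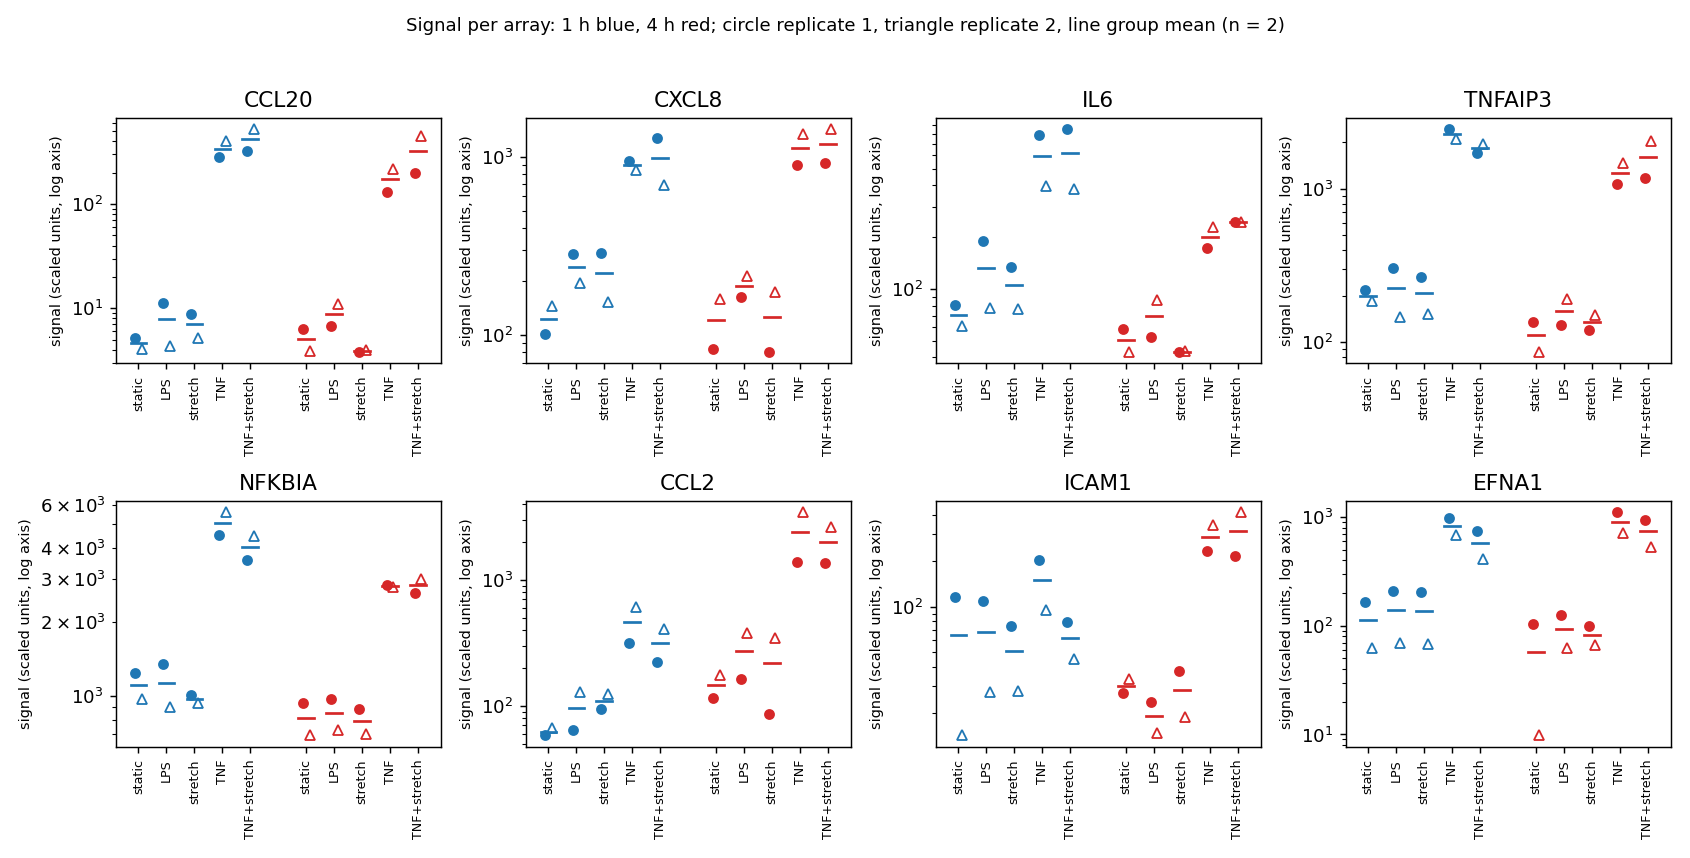
Signal (y axis, scaled units, log axis) of 8 genes on each array, by stimulus at 1 h (blue) and 4 h (red), with circles for replicate 1, open triangles for replicate 2 and lines for the mean of the 2 arrays. All 8 lie higher on every TNF and TNF+stretch array than on any static array of the same time, except ICAM1 at 1 h.

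TNF for 4 h was compared with static to ask what the cytokine does later. EFNA1, an ephrin ligand, rose by 4.29 (SE 0.80, adjusted p = 0.0424), by 3.30 within replicate 1 and 5.27 within replicate 2. Its signal was 104.6 in static replicate 1 and 9.8, close to the added value, in static replicate 2. In replicate 2 at 4 h it was 61.8 with LPS and 66.1 with stretch. The size of the EFNA1 rise therefore depends on that static array and on the added value. CCL2, the monocyte chemokine, rose by 3.85 (SE 0.66, adjusted p = 0.0243), from a signal of 146 ± 43.3 to 2410 ± 1457 (SD, n = 2). CCL20 rose by 3.69, TNFAIP3 by 3.43, CXCL8 by 3.16 and the survival gene BCL2A1 by 3.41. IL15RA rose by 2.66, IL32 by 2.20, the vitamin D receptor VDR by 1.86, and NFKB1, a subunit of NF-kB, by 1.81. NFKBIA and IFNGR2 each rose by 1.79, IRF1 by 1.59, NCK1 by 1.31 and SERPINB9, an inhibitor of granzyme B, by 1.21. In all 17 probe sets passed, all higher, of which 15 are these named genes and 2 are probe sets without a named gene. TNFRSF1A differed by −0.14 (SE 0.57) and TLR4 by −0.19 (SE 0.49), and neither passed. With the replicate block 103 passed, 88 higher and 15 lower. These included ICAM1 at 2.91, GCH1, the first enzyme of tetrahydrobiopterin synthesis, at 2.77, TNFAIP2 at 2.62, TNIP1 at 2.41, NINJ1 at 2.36, IFIH1 at 2.31 and HLA-B at 2.24. The lower ones with the block included SMAD6, an inhibitor of BMP signalling, at −1.45 (adjusted p = 0.000216), RGS2 at −1.28, ATXN2 at −1.27, RAB40B at −1.05, SLC20A1 at −1.01, TACC2 at −1.0, the death-associated kinase DAPK1 at −0.91, ITPRID2 at −0.85, SUCO at −0.84 and SH3BP5 at −0.81.

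Grouped by list, NF-kB target genes rose at 4 h of TNF, with 5 of 21 past the threshold, 14 adjusted over the list alone and all 21 above 0 (median 1.59, adjusted p = 1.52e-37, and 4.85e-05 with an estimated correlation). The cytokine list rose with 4 of 20 past the threshold and 11 adjusted over the list alone (adjusted p = 1.59e-24, and 2.38e-05 with an estimated correlation). The interferon response list rose, with all 24 tested members above 0 and a median of 1.04 (adjusted p = 9.72e-09). That call was lost with an estimated correlation (adjusted p = 0.469) and held there with the replicate block (adjusted p = 0.0188). None of its members passed without the block, where 2 did adjusted over the list alone, and 6 passed with it, among them the antiviral sensors IFIH1 at 2.31 and RIGI at 1.45 and the interferon-induced gene IFIT3 at 2.00. Antigen presentation genes rose as a list (median 0.65, adjusted p = 0.00119, and 0.547 with an estimated correlation). With the block this list had an adjusted p of 0.0237 with an estimated correlation, and 4 of 12 passed, HLA-B, HLA-C, TAPBP and PSMB9. Matrix, adhesion and proteolysis genes rose as a list (adjusted p = 0.00318, and 0.159 with an estimated correlation, or 0.0302 with the block and an estimated correlation), and 3 of 17 passed with the block, the urokinase gene PLAU at 1.71, the laminin chain LAMB3 at 1.62 and COL4A1 at 1.08. The apoptosis list rose (adjusted p = 0.0121, and 0.168 with an estimated correlation), where BID passed with the block at 1.18. Immediate early genes (adjusted p = 0.0374) and cell cycle genes (adjusted p = 0.0374) passed without the block, and both were lost with an estimated correlation (adjusted p = 0.314 and 0.790), the former with the block too (adjusted p = 0.0526). Cholesterol biosynthesis genes were lower as a list with the block alone (adjusted p = 0.024, and 0.130 with an estimated correlation). Leaving out 1 array gave 3 probe sets without static replicate 2, 5 without static replicate 1, 0 without TNF replicate 2 and 2 without TNF replicate 1, and 64, 36, 51 and 40 in that order with the block.

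The change of the TNF response from 1 h to 4 h was tested directly as a difference of differences. With limma no probe set passed, and 92 had an unadjusted p under 0.05. The replicate block gave 1, and 316 had an unadjusted p under 0.05. That was TNIP1, which encodes a partner of A20, with a TNF effect 2.21 greater at 4 h than at 1 h (SE 0.33, adjusted p = 0.0484 with the block). The count with the block is not stable: leaving out 1 array gave 0 in 6 of 8 fits, 1 in another and 3 in the last, and leaving out the 3 arrays of high ratio, none of them in this comparison, gave 0. The 5 with the smallest p did not pass: VDR at 2.07, IL15RA at 2.67, NFKB1 at 1.64, IL32 at 2.16 and NPFFR1 at 1.45. As lists, the response was greater at 4 h for interferon response genes (median 1.04, adjusted p = 2.84e-06), NF-kB target genes (median 0.95, adjusted p = 1.04e-05) and antigen presentation genes (median 0.75, adjusted p = 0.00982). It was greater too for cell cycle genes (adjusted p = 0.00982) and matrix genes (adjusted p = 0.0115), and lower for ribosomal protein genes (adjusted p = 8.57e-08). With an estimated correlation none of these passed, with adjusted p of 0.560, 0.180, 0.566, 0.683, 0.428 and 0.435 in that order. All 6 passed with the block, and with the block and an estimated correlation none did (lowest adjusted p = 0.0638). Cholesterol biosynthesis genes were lower with the block alone (adjusted p = 0.00888, and 0.105 with an estimated correlation).

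LPS, which acts on cells through TLR4 with its partner CD14, was compared with static to ask what the bacterial product alone does to these cells. No probe set passed in limma at 1 h or at 4 h, and 39 and 34 had an unadjusted p under 0.05. With the replicate block none passed either, and 250 and 130 had an unadjusted p under 0.05. With the block, 5 passed at 1 h without static replicate 2 and 1 at 4 h without static replicate 1. The intervals given here are from the fit without the block. At 1 h CXCL8 differed by 0.91 (95% interval −0.08 to 1.90) and at 4 h by 0.66 (−0.33 to 1.65). With the block the interval of CXCL8 is narrower and lies above no difference at both times. That interval is not adjusted for the number of genes, and CXCL8 passed at neither time. ICAM1 differed by 0.29 (−1.32 to 1.91) and −0.49 (−2.11 to 1.12), TLR4 by 0.02 and −0.05, and TNFRSF1A by −0.07 and −0.16. The genes with the smallest p at 1 h were SH3BP2 at 1.24, ZNF286A at −1.53, ACTC1 at 1.02, ADAMTS2 at −1.21 and ARR3 at −0.99, and none passed. At 4 h they were KPNA4, a nuclear import factor, at 1.54, ANXA6 at −0.85, SLC5A5 at 1.26, RYK at 0.98 and DEFA5 at −1.14, and none passed. CD14 was dim in all groups, with a median signal of 9.9 and no array above the median of all values, and TLR4 had a median signal of 36.15 and exceeded that value in 6 of 20 arrays. The adaptor MYD88, with a median signal of 312.75, exceeded it in all 20.

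As a list, cytokines and chemokines were higher with LPS at 1 h (median 0.25, 14 of 20 above 0, adjusted p = 0.0135) and at 4 h (median 0.25, 15 of 20 above 0, adjusted p = 0.0123). Both calls were lost with an estimated correlation (adjusted p = 0.206 and 0.143), and none of their members passed over all probe sets. Adjusted over the list alone none passed either, except 2 at 1 h with the block. The GAPDH ratio of LPS replicate 2 at 4 h was 3.19, against 2.18 for static replicate 2, and without the 3 arrays of high ratio the list at 4 h had an adjusted p of 0.468 with the block. The fit without those 3 arrays has 1 LPS array at 4 h. NF-kB target genes did not pass with LPS, with or without the block.

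Stretch to 20% elongation was compared with static to ask what mechanical load alone does. No probe set passed in limma at 1 h or 4 h, with 44 and 31 at an unadjusted p under 0.05, and none passed with the replicate block, with 256 and 123. Leaving out static replicate 2 at 1 h with the block gave 3. CXCL8 differed by 0.76 at 1 h (95% interval without the block −0.23 to 1.75) and by 0.03 at 4 h (−0.96 to 1.02), and ICAM1 by 0.05 and −0.12. With the block the interval of CXCL8 at 1 h is narrower and lies above no difference, without adjustment for the number of genes, and CXCL8 did not pass. TLR4 differed by −0.06 and 0.06, and TNFRSF1A by −0.03 and 0.11. At 1 h the smallest p belonged to SH3BP2 at 1.30, the DNA repair gene XRCC2 at −1.21, the chemokine CXCL5 at 0.87, MIR9-1HG at −1.23 and HCFC1 at 0.74, none of which passed. At 4 h it belonged to NPFFR1 at 0.85, SGPP1 at −0.68, KPNA4 at 1.07, HHLA1 at 1.69 and IL2RA at −1.71, none of which passed. The cytokine list was higher at 1 h (median 0.21, 15 of 20 above 0, adjusted p = 0.008), a call lost with an estimated correlation (adjusted p = 0.161), and no member passed. With the block alone, immediate early genes were higher (adjusted p = 0.0254) and cell cycle genes lower (adjusted p = 0.0151) at 1 h, both with an adjusted p of 0.448 with an estimated correlation. Target genes of YAP and SRF, regulators that respond to mechanical load, did not pass in any of the 17 comparisons.

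Ribosomal protein genes were higher with every stimulus at 1 h, by medians of 0.22 with TNF, 0.25 with LPS, 0.22 with stretch and 0.28 with TNF+stretch. Their adjusted p was 1.62e-09, 4.95e-14, 2.06e-08 and 9.90e-13, and with an estimated correlation it was 0.432, 0.382, 0.484 and 0.251, so that each call was lost. Under quantile normalization the medians were smaller, 0.14, 0.18, 0.14 and 0.12, and the calls held and were lost with an estimated correlation in the same way (adjusted p = 0.405, 0.289, 0.475 and 0.293). No single ribosomal protein gene passed, over all probe sets or adjusted over the list alone. The static array of replicate 1 at 1 h, shared by these comparisons, had a GAPDH ratio of 1.75, above the 0.939 to 1.28 of the other 1 h arrays of replicate 1. In the direct test of TNF and stretch together against the sum of each at 1 h, this list was lower (adjusted p = 0.012, and 0.991 with an estimated correlation).

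**Figure D3:**
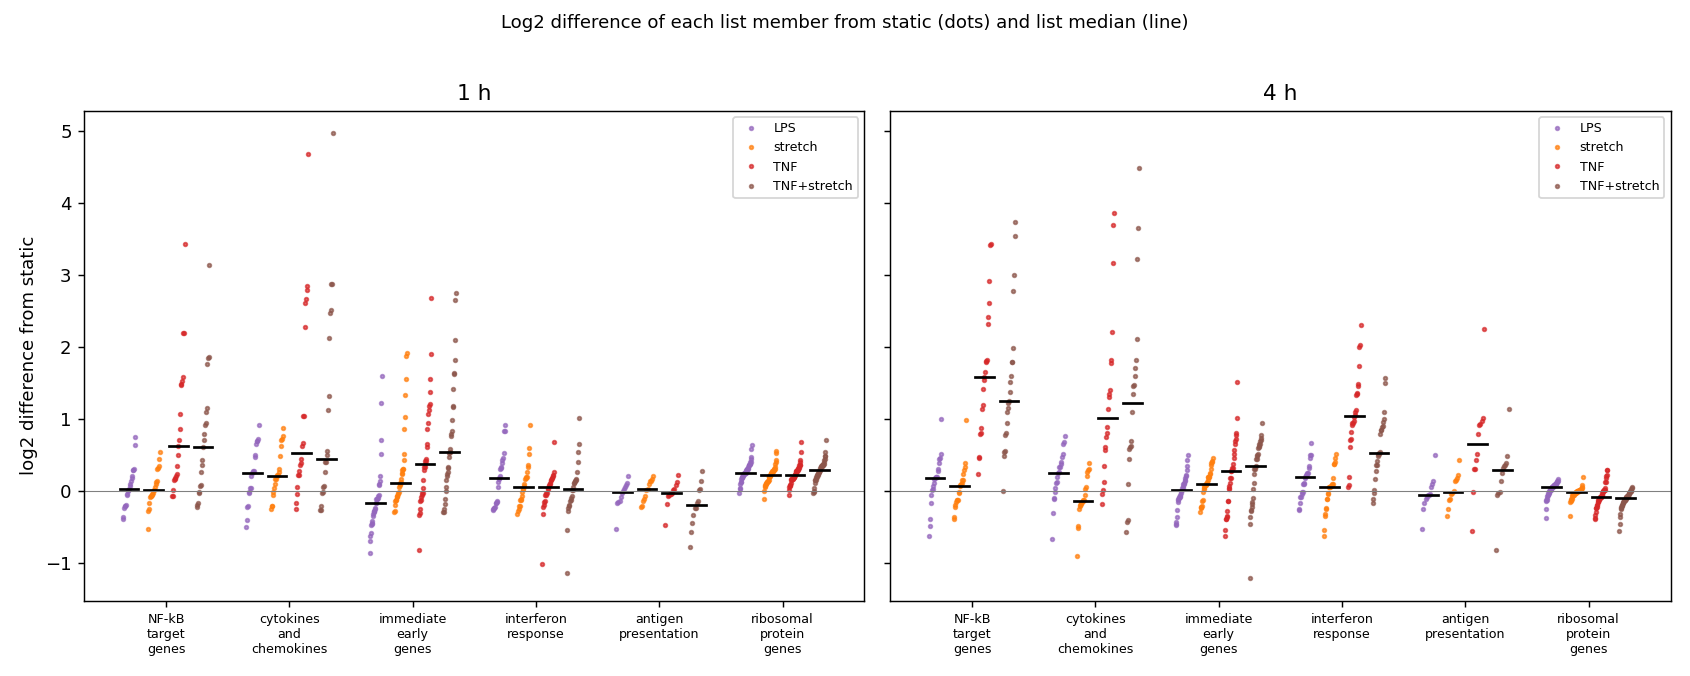
Log2 difference from static (y axis) of each tested member of 6 gene lists (points) with the list median (line), for 4 stimuli at 1 h (left) and 4 h (right). With TNF the NF-kB target genes have a median of 0.62 at 1 h and 1.59 at 4 h, and the interferon response genes 0.06 and 1.04.

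TNF and stretch together were compared with static and raised chemokine genes and the NF-kB inhibitor genes TNFAIP3 and NFKBIA, among others. At 1 h 7 probe sets passed, all higher: CCL20 at 4.97 (SE 0.40, adjusted p = 6.83e-05), TNFAIP3 at 3.13, IL6 at 2.88, CXCL8 at 2.87, CXCL2 at 2.52, CXCL3 at 2.47 and NFKBIA at 1.86. At 4 h 14 passed, all higher, among them CCL20 at 4.48 (SE 0.40, adjusted p = 0.000236), TNFAIP3 at 3.74, CCL2 at 3.65, BCL2A1 at 3.54 and CXCL8 at 3.22. The others named were VDR at 1.86, NFKBIA at 1.80, IFNGR2 at 1.62, NFKB1 at 1.60, IRF1 at 1.51, SERPINB9 at 1.43 and NCK1 at 1.25. With the replicate block 13 passed at 1 h and 62 at 4 h. Among those added by the block at 1 h were EFNA1 at 2.35, CCL2 at 2.12, ZFP36 at 1.64, IRF1 at 1.10, NFIL3 at 0.93 and CCNL1 at 0.88. At 4 h they included EFNA1 at 3.97, a size that depends on the dim static replicate 2 array, as it does with TNF. They also included ICAM1 at 3.0, GCH1 at 2.80, PTX3 at 2.78 and MAFF at 2.60. Further ones were IL15RA at 2.19, IL6 at 2.11, the cyclooxygenase gene PTGS2 at 2.07 and TNIP1 at 1.99. The 3 lower ones with the block were CHD1L at −1.54, TRADD, an adaptor of the TNF receptor, at −1.07 and TRIB3 at −0.81. TNFRSF1A differed by −0.20 at 1 h and −0.41 at 4 h, TLR4 by 0.34 and −0.46, and ICAM1 at 1 h by 0.36, none of which passed.

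By list, NF-kB target genes and cytokines rose with the combination at both times, and both calls held with an estimated correlation. The adjusted p for NF-kB target genes was 1.13e-14 at 1 h and 2.21e-36 at 4 h, with 2 and 5 of 21 past the threshold and 5 and 10 adjusted over the list alone. For cytokines it was 3.81e-20 and 1.34e-26, with 5 and 3 of 20 past the threshold and 6 and 11 adjusted over the list alone. Immediate early genes rose at 1 h (median 0.53, adjusted p = 4.34e-12, and 0.00177 with an estimated correlation), with no member past the threshold and 1 adjusted over the list alone. At 4 h this list (adjusted p = 0.0094), interferon response genes (0.000205), matrix genes (0.00313) and, downwards, ribosomal protein genes (0.047) passed and were lost with an estimated correlation, with adjusted p of 0.171, 0.828, 0.145 and 0.914. Under quantile normalization matrix genes held with an estimated correlation (adjusted p = 0.0447), and ribosomal protein genes were lost with the preset correlation too (adjusted p = 0.527). With the block alone, antigen presentation genes were higher at 4 h (adjusted p = 0.0049), and cell cycle genes were lower at 1 h (0.0285) and at 4 h (0.00505), with adjusted p of 0.253, 0.451 and 0.255 with an estimated correlation. Leaving out 1 array gave 3 probe sets without static replicate 2, 1 without static replicate 1, 1 without TNF+stretch replicate 2 and 5 without its replicate 1 at 1 h, and 3, 5, 2 and 2 in that order at 4 h, with 8 to 21 and 37 to 49 with the block. Without the 3 arrays of high 3' to 5' ratio, both times had 1 probe set (10 and 40 with the block), and each then rests on a single TNF+stretch array.

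What stretch added to TNF was tested directly. No probe set passed in limma at 1 h or 4 h, with 44 and 56 at an unadjusted p under 0.05, and none passed with the replicate block, with 162 and 345. At 4 h the combination differed from TNF alone by 0.79 for CCL20 (95% interval 0.01 to 1.57 with the block), 0.06 for CXCL8 (−0.51 to 0.63), 0.29 for IL6 (−0.23 to 0.80), 0.09 for ICAM1 (−0.77 to 0.95) and 0.01 for NFKBIA (−0.44 to 0.46). At 1 h it differed by 0.29 for CCL20 (−0.49 to 1.06), 0.07 for CXCL8 (−0.50 to 0.65), 0.03 for IL6 (−0.49 to 0.54) and −0.33 for NFKBIA (−0.78 to 0.12). Of the genes called against static at 1 h, the interval left out 0 for ZNF443 at −1.23 (−1.77 to −0.69), MYC at 0.57 (0.23 to 0.91) and IRF1 at −0.43 (−0.80 to −0.06), and none passed. Among the genes called against static with TNF or TNF+stretch at 4 h in either fit, those that differed by more than 1 in size, a bound set after the values were seen, were CHD1L at −1.39 (−2.09 to −0.68), TRADD at −1.37 (−1.88 to −0.87), NAP1L4 at −1.31 (−1.82 to −0.80), IFIT3 at −1.21 (−2.11 to −0.32) and HLA-B at −1.10 (−1.82 to −0.38), with intervals from the block. Each had the same sign in both replicate pairs and none passed, the smallest adjusted p with the block being 0.203 for TRADD and NAP1L4. All of them were lower with the combination, but smaller differences whose interval left out 0 went both ways. Examples are MAFF at 0.79 (0.18 to 1.39) and SMAD6 at 0.77 (0.41 to 1.14). On the lower side are TNFAIP2 at −0.82 (−1.52 to −0.13) and PSMB9 at −0.61 (−1.04 to −0.18), and none of these passed. These genes, like those at 1 h, were taken for passing against static with a group compared here. That choice can widen the difference by itself, so an interval without 0 is not a test. The genes with the smallest p at 4 h without the block were ST3GAL2 at 1.59, NELL2 at 1.52, METTL13 at −0.96, MAGEB2 at 1.40 and JPT1 at −0.75, and at 1 h RGS19 at 0.78, MMP26 at 0.97, HTR3A at −1.03, GRK6 at −1.23 and SLC29A2 at 1.69, none of which passed. Leaving out TNF+stretch replicate 1 at 4 h gave 1 probe set, and 3 with the block.

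As lists, cell cycle genes were lower with the combination than with TNF at 4 h (median −0.48, adjusted p = 3.15e-06, and 0.922 with an estimated correlation). With the block, interferon response genes (median −0.47, adjusted p = 3.17e-07) and antigen presentation genes (median −0.34, adjusted p = 3.64e-05) were lower too. Without it their adjusted p was 0.0606 and 0.2, and under quantile normalization without it that of the interferon list was 0.0230 (adjusted p = 0.854 with an estimated correlation). With an estimated correlation in that fit the adjusted p was 0.233 for interferon response genes, 0.192 for antigen presentation genes and 0.087 for cell cycle genes. The GAPDH ratio was 4.89 in TNF+stretch replicate 2 at 4 h and 1.45 in TNF replicate 2. Leaving out the 3 arrays of high ratio leaves TNF+stretch at 4 h with 1 array, so that fit cannot decide if these calls depend on the ratio. At 1 h, immediate early genes were higher with the combination with the block alone (adjusted p = 0.0193, and 0.770 with an estimated correlation). The interaction, which asks if the combination departed from the sum of the log2 effects, had no probe set past the threshold in limma at 1 h or 4 h (27 and 43 at an unadjusted p under 0.05) or with the block (146 and 219). Its smallest p belonged at 1 h to L1CAM at 1.07, MIR9-1HG at 1.76, ACAN at 1.32, SLC29A2 at 2.33 and NPFFR1 at 1.03, and at 4 h to ATXN2 at 1.23, the mitotic kinase AURKB at −1.38, GRK6 at −1.88, CD22 at 1.69 and NAP1L4 at −1.76, none of which passed. Cell cycle genes were lower in the interaction at 4 h (adjusted p = 0.000898, and 0.857 with an estimated correlation), and with the block alone so were interferon response genes (0.00017, and 0.520 with an estimated correlation) and antigen presentation genes (0.000684, and 0.372 with an estimated correlation). The cytokine list was lower in the interaction at 1 h under quantile normalization (adjusted p = 0.0454, and 0.388 with an estimated correlation), and did not pass without it (0.0606).

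TNF was tested directly against LPS and against stretch, which asks if the cytokine's effect exceeds theirs. At 1 h 6 probe sets were higher with TNF than with LPS, among them CCL20 by 4.40 (SE 0.40, adjusted p = 0.000291), TNFAIP3 by 3.37, CXCL3 by 2.33, NFKBIA by 2.18 and ZFP36 by 2.06. The sixth was IRF1, at 1.72. Against stretch 6 were higher, with CCL20 at 4.46 (SE 0.40, adjusted p = 0.000252), TNFAIP3 at 3.42, CXCL3 at 2.85, NFKBIA at 2.36, ZFP36 at 2.04 and IRF1 at 1.57. At 4 h 4 were higher than with LPS: CCL20 at 3.36 (SE 0.40, adjusted p = 0.00666), TNFAIP3 at 2.93, NFKBIA at 1.73 and a probe set without a named gene. The next were IFNGR2 at 1.70, IL15RA at 2.50, NFKB1 at 1.54, IRF1 at 1.41 and CXCL8 at 2.50, each with an adjusted p of 0.0502. Against stretch 14 were higher at 4 h, among them CCL20 at 3.82 (SE 0.40, adjusted p = 0.00154), CCL2 at 3.57, TNFAIP3 at 3.14, CXCL8 at 3.13 and BCL2A1 at 3.03. The replicate block gave 18 and 15 at 1 h, and 79 and 92 at 4 h, and leaving out 1 array with it gave 10 to 16 in both at 1 h, and 22 to 34 against LPS and 37 to 49 against stretch at 4 h. The block added EFNA1 in each of these 4 comparisons, at 2.67 and 2.69 at 1 h and 3.20 and 3.31 at 4 h, and ICAM1 at 3.41 against LPS at 4 h. It also added IL6 against stretch at 1 h at 2.36, and CCL2 and BCL2A1 against LPS at 4 h at 3.09 and 2.95. Lower with TNF, with the block, were MYC at −0.88 against stretch at 1 h, SMAD6 at −1.49 and −1.21, RGS2 at −1.35 and −1.23 and SLC20A1 at −0.98 and −1.05 against LPS and stretch at 4 h. SRPK2 at −0.93 and CHST3 at −0.86 were lower than with LPS, and SP2 at −1.0 and TACC2 at −0.95 lower than with stretch.

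**Figure D4:**
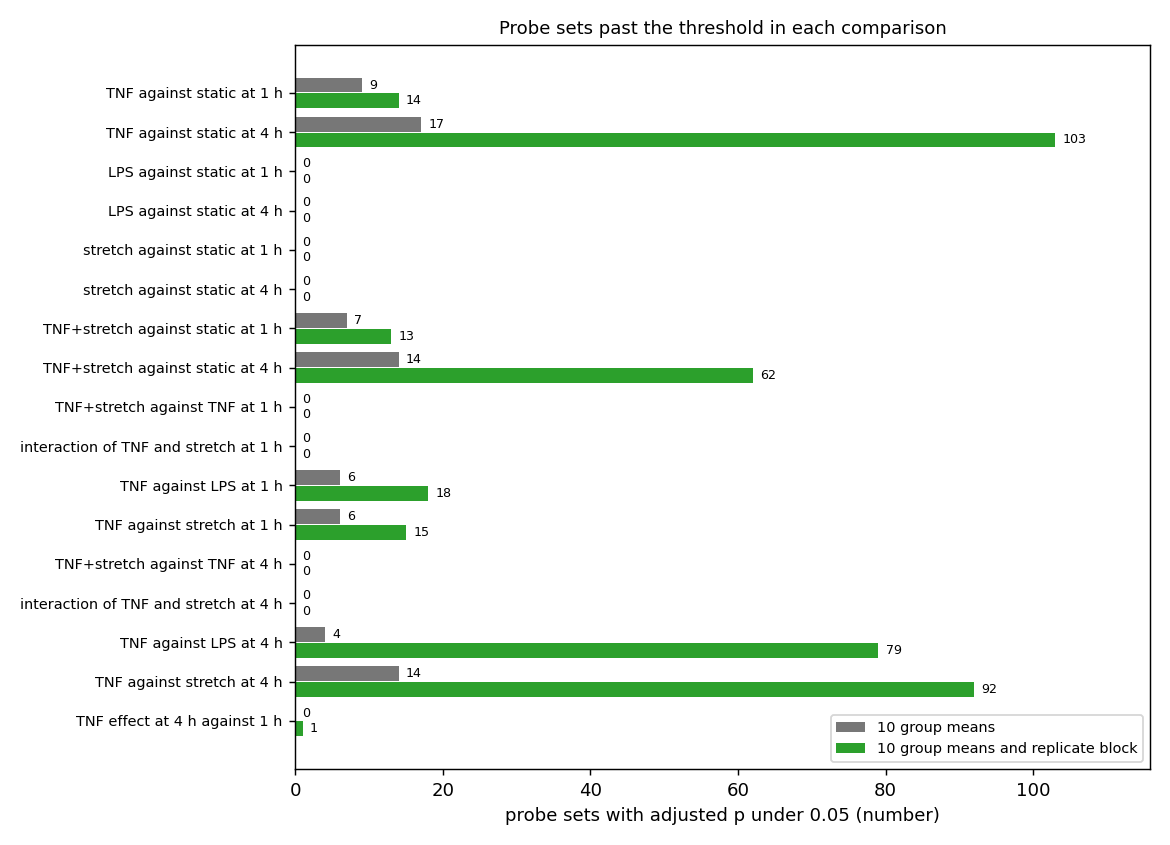
Number of probe sets past the threshold (x axis) in each of the 17 comparisons (y axis), in the fit of 10 group means (grey) and with the replicate block added (green). TNF against static at 4 h has 17 and 103, and each comparison of LPS or stretch with static has 0.

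By list, NF-kB target genes and cytokines were higher with TNF than with LPS or stretch at both times, with adjusted p between 9.68e-39 and 4.50e-20, and all 8 calls held with an estimated correlation in both fits. Of the 21 NF-kB target genes, 3 passed against LPS and 3 against stretch at 1 h, and 2 and 5 at 4 h. Adjusted over the list alone these were 5, 6, 10 and 13. Of the 20 cytokines, 2, 2, 1 and 5 passed, and 7, 6, 8 and 11 did adjusted over the list alone. Immediate early genes were higher than with LPS at 1 h (median 0.51, adjusted p = 6.44e-12, and 0.0012 with an estimated correlation) and than with stretch (adjusted p = 0.00246, and 0.111 with an estimated correlation), a call lost with the block (adjusted p = 0.0615). At 4 h interferon response genes were higher than with LPS (adjusted p = 2.41e-07) and stretch (1.34e-09), and so were antigen presentation genes (4.37e-05 and 0.0011). These were lost with an estimated correlation (adjusted p = 0.450, 0.722, 0.368 and 0.722) and held there with the block (0.0217, 0.0159, 0.014 and 0.0203). Matrix genes (adjusted p = 0.00755 and 0.0127) and cell cycle genes (0.00382 and 0.0462) were higher than with LPS and stretch at 4 h, and apoptosis genes than with LPS (0.0264), and all were lost with an estimated correlation (adjusted p = 0.239, 0.276, 0.691, 0.966 and 0.261). Matrix genes against LPS held with an estimated correlation with the block (0.0448). Cholesterol genes were lower with the block alone (0.00286 and 0.00894, and 0.0543 and 0.0874 with an estimated correlation), as were ribosomal protein genes against LPS (0.0258, and 0.578 with an estimated correlation). Leaving out 1 array gave 1 to 4 probe sets against LPS and 3 against stretch at 1 h, and 0 to 1 and 0 to 4 at 4 h. The 0 against LPS at 4 h came without LPS replicate 2 or TNF replicate 2, and that against stretch without TNF replicate 2.

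A further set of lists did not pass in any of the 17 comparisons in either fit, with the smallest adjusted p of the 2 fits as follows. It was 0.207 for YAP and SRF targets, 0.382 for heat shock proteins, 0.199 for the unfolded protein and integrated stress response, 0.412 for NRF2 targets, 0.0636 for glycolysis and hypoxia, 0.375 for DNA replication and 0.159 for p53 targets. Under quantile normalization NRF2 targets passed for the TNF effect at 4 h against 1 h (adjusted p = 0.0400, and 0.491 with an estimated correlation). For LPS recognition (7 tested genes) it was 0.267, for alveolar epithelial genes (8) 0.318, for epithelial junction genes (10) 0.162 and for leukocyte markers (7) 0.182. With TNF at 4 h the junction gene CLDN1 was higher with the block at 1.31 (adjusted p = 0.0439), as the 1 of its 10 listed genes to pass. Of the fibroblast markers 3 and of the endothelial markers 1 were bright enough to test, too few for a test of the list. Of 2 surfactant genes that mark type II cells, SFTPC had a median signal of 40.85 and SFTPB, at 16.85, was not tested.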

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

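Chosen after the result was seen were the within-replicate tests of the combination on either set of probe sets and the test on ribosomal protein genes. So was the reading of tests as undecided where their own bound had been met or could not be applied.

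On 4 replicate 2 arrays the 3' to 5' ratio of both control transcripts exceeded that of every static array, where the highest was 2.18 for GAPDH and 9.37 for actin. The GAPDH ratio was 3.19 for LPS at 4 h, 2.59 for stretch at 4 h, 3.21 for TNF+stretch at 1 h and 4.89 for TNF+stretch at 4 h. The actin ratio on these arrays was 13.8, 9.42, 14.1 and 20.4. The TNF effect on TNIP1 was greater at 4 h than at 1 h by 2.21 (SE 0.33, adjusted p = 0.0484 with the replicate block), a difference tested directly that did not pass without the block.

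Interferon response genes were higher in replicate 1 than in replicate 2 of the 1 h groups, by a median of 2.00 with 22 of 24 past the threshold. The drawn splits do not exclude chance. Of 100 drawn splits of the 10 arrays, 1, the real one, gave as many probe sets, 2232, and the highest other gave 1137. Only the 14 drawn splits that part all 5 pairs are like the real one, which is too few to decide. All of these but the real one gave 0, which the replicate difference in their residual spread favours. The counts also cover all probe sets and not the interferon list alone. With the GAPDH ratio as a covariate the median was 1.87 (lower bound 1.33, against a bound of 1.00), an interval over genes and not over arrays. In that fit to the arrays 22 of 24 still passed, all higher in replicate 1. This argues against RNA quality as measured by the GAPDH ratio as the whole cause. The chip lot stays open, since replicate 1 at 4 h, on the same lot, differed by a median of 0.578 with an interval of 0.203 to 1.17 that includes 1.00. Another cell type stays open as well, since leukocyte markers differed by 0.0883 (upper bound 0.339) but the planned bound needed 3 marker lists and 1 could be tested, and no biological explanation was tested because the replicate numbers name none.

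Fewer probe sets passed for TNF+stretch (62) than for TNF (103) at 4 h with the replicate block, but without static replicate 1 the counts were 41 and 36, so the order turns with 1 array. Without the arrays of high 3' to 5' ratio the counts still had a ratio of 2.3, above the planned bound, but that leaves TNF+stretch with 1 array, which lowers its count by itself, so the test cannot decide. Within replicate 1, where the ratios are low, the combination differed from TNF in the direction of the response by a median of −0.0768 (−0.126 to −0.0337) over 112 probe sets and −0.0442 (−0.0937 to −0.0123) over 114 chosen on the mean of both groups, and within replicate 2 by −0.151 (−0.327 to −0.0425) and −0.109 (−0.200 to 0.0614, which includes 0). These met the bound written against RNA quality, but that bound was wrong, since the interval covers genes and not cultures and there is 1 array per group. The median ratio of the log2 differences, 0.886 (0.821 to 0.948) over the 103 probe sets, decides nothing, since they were chosen for passing with TNF and a ratio below 1 follows from that choice alone, and with 0 of them called in the direct comparison RNA quality, stretch and the static array all stay open.

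Ribosomal protein genes were higher than in static with every stimulus at 1 h, calls that are all lost with an estimated correlation (adjusted p = 0.432, 0.382, 0.484 and 0.251), and all 4 comparisons of replicate 1 share 1 static array with a GAPDH ratio of 1.75. Within replicate 1 the medians were 0.408 for TNF, 0.446 for LPS, 0.287 for stretch and 0.423 for TNF+stretch, and within replicate 2 they were 0.102, 0.0965, 0.147 and 0.212. The bound chosen for that static array as the cause was each replicate 2 median under 0.5 times that of replicate 1. It held for TNF and LPS and was narrowly missed for stretch and TNF+stretch. The comparisons of replicate 2 also share 1 static array, so a rise there cannot tell a common effect from that array. The highest replicate 2 median, 0.212, therefore decides neither way, and an early effect common to the stimuli stays open and untested.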

How the results depend on the processing

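The offset as a floor and quantile normalization kept every count within 1.5 times, except 8 for TNF against LPS at 4 h with quantile normalization. Without the filter TNF against LPS at 4 h had 7 and the TNF effect at 4 h against 1 h had 1. The replicate block gave, for 1 h and 4 h, 14 and 103 for TNF, 13 and 62 for TNF+stretch, 18 and 79 for TNF against LPS, 15 and 92 for TNF against stretch, and 1 for the TNF effect. The block removes the spread between replicate sets, and its median SE was 0.238 against 0.387. With only the arrays of the same time, which leaves fewer degrees of freedom, TNF had 3 and 0, TNF+stretch 2 and 2, TNF against LPS 3 and 0, and TNF against stretch at 4 h 0.

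Chosen after seeing the data, leaving out the 3 arrays with a GAPDH ratio above 3 gave 5 and 2 for TNF, 1 and 1 for TNF+stretch, 1 for TNF against LPS at 4 h and 7 for TNF against stretch at 4 h. The same with the block gave 15 and 92 for TNF, 40 for TNF+stretch at 4 h, 18 and 24 for TNF against LPS and 15 and 79 for TNF against stretch. The block with the ratio as a covariate gave 16 and 115 for TNF, 17 and 65 for TNF+stretch, 21 and 77 for TNF against LPS, 19 and 96 for TNF against stretch, and 6 for the TNF effect. The 3 arrays left out are of LPS and TNF+stretch, so the differences of TNF from static and from stretch are the same without them. The counts of those comparisons moved through the estimate of the spread and its degrees of freedom. For the other comparisons, and for the covariate, the cause was not tested.

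Leaving out 1 array gave 2 to 5 and 0 to 5 for TNF, 1 to 5 and 2 to 5 for TNF+stretch, 1 to 4 and 0 to 1 for TNF against LPS, 3 to 3 and 0 to 4 for TNF against stretch, and 0 to 1 for TNF+stretch against TNF at 4 h. Here the lone array of a group is assumed to vary like the other groups. Each comparison of LPS or stretch with static stayed at 0 under all of these settings without the block; with the block and 1 array left out they reached at most 5. The count with the block and 1 array left out was 22 to 34 for TNF against LPS and 37 to 49 for TNF against stretch at 4 h.

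Named results that turned sign passed in no setting in which they turned, and reached −1.17 for ICAM1 with stretch at 1 h; the cause was not tested. With the block and the covariate TNFRSF1A was −0.088 for TNF at 1 h. Without the arrays of high ratio TNFRSF1A was 0.38 for LPS at 4 h, 0.34 for TNF+stretch at 1 h and 0.21 at 4 h, and TLR4 −0.27 for TNF+stretch at 1 h, and with the block TNFRSF1A was 0.37, TLR4 −0.0393 and ICAM1 −0.0736, all for TNF+stretch at 1 h. Leaving out 1 array, CXCL8 ranged from −0.49 to 0.55 for stretch at 4 h. ICAM1 ranged from −0.92 to 1.51 for LPS at 1 h, −0.85 to 1.58 for TNF+stretch at 1 h, −1.17 to 1.27 for stretch at 1 h and −0.50 to 0.25 at 4 h. TLR4 ranged from −0.10 to 0.15 and −0.37 to 0.26 for LPS at 1 h and 4 h, −0.83 to 0.41 and −0.51 to 0.12 for TNF, −0.27 to 0.94 for TNF+stretch at 1 h, and −0.56 to 0.44 and −0.25 to 0.38 for stretch. TNFRSF1A ranged from −0.18 to 0.0459 and −0.78 to 0.46 for LPS, −0.0567 to 0.16 and −0.76 to 0.48 for TNF, −0.74 to 0.34 and −1.04 to 0.21 for TNF+stretch, and −0.12 to 0.0672 and −0.52 to 0.73 for stretch.

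Of the values of named genes, 64 gained a call with the block and none lost one, and leaving out 1 array ended a call 173 times and kept the side of the threshold 644 times. The 64 does not measure what the block changes, since genes were also named for passing with it. Of the list results, 15 gained and 2 lost a call with the block, namely immediate early genes for TNF at 4 h (adjusted p = 0.0526) and against stretch at 1 h (0.0615), and 36 lost it with an estimated correlation. Quantile normalization, chosen for the lists after seeing the data, kept 54 of 55 list calls, turned none and gained 3, interferon response genes for TNF+stretch against TNF at 4 h (adjusted p = 0.0230), cytokines in the interaction at 1 h (0.0454) and NRF2 targets for the TNF effect at 4 h against 1 h (0.0400), all lost with an estimated correlation (adjusted p = 0.854, 0.388 and 0.491). Dim probe sets limit what can be seen, since a signal near 8.7 moves little on the scale tested.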

Other observations

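Many genes of several lists differed between replicate 1 and replicate 2 of these cells, given here as counts and medians without a test of the list. At 1 h, with the group in the model, 2232 of 5357 probe sets differed between replicate 1 and replicate 2 in limma, 1094 higher and 1138 lower in replicate 1. In these fits, at 1 h and at 4 h, the arrays of the 5 groups serve as replicates. Their p-values thus measure the spread between arrays within a replicate set and not that between repeats of the experiment. Interferon-induced genes were among the highest, with ISG15, a ubiquitin-like antiviral protein, higher in replicate 1 by 5.31 (SE 0.37, adjusted p = 1.41e-05), IFITM3, which blocks virus entry, by 4.81, IFIT1 by 4.27 and MX1 by 3.13, and each was higher in replicate 1 in all 5 groups. Antigen presentation genes were higher by a median of 1.05 with 10 of 12 past the threshold, and all 12 genes of the unfolded protein and integrated stress response passed, with a median of 1.22. Cholesterol biosynthesis genes were lower in replicate 1 by a median of −1.23 with 11 of 14 past the threshold, DNA replication genes by −0.91 with 16 of 20, and cell cycle genes by −0.73 with 18 of 24.

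At 4 h, where the 4 replicate 1 arrays with a record were scanned on another day than those at 1 h, 2822 probe sets differed between the replicates. DNA replication genes were lower in replicate 1 by a median of −1.49 with 17 of 20 past the threshold, and cell cycle genes by −0.89 with 18 of 24. Stress response genes were higher by 0.84 with 10 of 12, and interferon response genes by 0.58 with 12 of 24, among them IFITM3 by 3.04. With the GAPDH ratio as a covariate 1946 probe sets differed at 1 h and 378 at 4 h. At 4 h the ratio was higher in replicate 2 in every group, so that fit separates the ratio and the replicate poorly. The fall to 378 therefore does not show that the ratio is the source of the differences at 4 h. At 1 h the interferon list had 22 of 24 past the threshold with the covariate. At 4 h 14 of 20 DNA replication genes were past it with the covariate (median −1.16), and 2 of 24 cell cycle genes (−0.57), 2 of 12 stress response genes (0.68) and 2 of 24 interferon response genes (0.57). Replicate 1 and replicate 2 differ in day and chip lot at once and in their median RNA ratios, so these differences have no single named source in the records. At 1 h the ratio does not follow the replicate in every group. The GAPDH ratio there was higher in replicate 1 for static (1.75 against 1.40) and TNF (1.28 against 1.18). For the interferon list at 1 h, the 22 of 24 past the threshold with the covariate argue against the GAPDH ratio as the whole source.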
